A study of Populus deltoides with 11 samples.

How the data were processed

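Small RNAs were sequenced from leaf, cambium, phloem and xylem of 7-year-old *Populus deltoides* (eastern cottonwood) trees of a single clone. Per the labels, stem pieces came from 3 replicate trees. The labels do not say which tree gave which library, so libraries of different tissues may share a tree. P-values measure the spread between libraries from trees of that clone, which also holds differences of dissection and library making. The 11 libraries analysed here comprise 3 of leaf, 3 of cambium, 3 of phloem and 2 of xylem. No further xylem library is analysed here.

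Per the labels' protocols, total RNA was isolated with TRIzol, RNA of 18 to 30 nt was taken from a gel, adaptors were ligated to both ends, and the amplified library band of 145 to 160 bp, described as inserts of 22 to 30 nt, was recovered and sequenced as 50-nt single-end reads. The submitters' processing notes name cutadapt 1.18 and Bowtie 1.2.2 without giving their role. The genome build is not given in the sources used here. Each deposited file lists distinct read sequences (tags) with a whole-number count of reads, and the deposited counts are not normalized. The libraries carry no molecular identifiers, so PCR copies cannot be removed from these counts, and every interval or floor given below covers counting error only.

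Tags of 18 to 30 nt without ambiguous bases were kept. The depth per library was 19159662 to 25717283 reads: 23843002 to 25717283 in leaf, 22985540 to 25529062 in cambium, 22700473 to 24985152 in phloem and 19159662 to 22183002 in xylem. A floor of 3 counts corresponds to 0.157 CPM in the shallowest library before TMM scaling. Over all libraries, 32827223 distinct tags were seen, of which 898947 had at least 15 reads in total. These held 78.4% of the reads. Counts of libraries of the same tissue differed by far more than sampling noise, with a chi-square per degree of freedom of 31.5 to 386 over pairs, so no library was counted as a repeat of another.

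MicroRNA families were counted directly from the tags, since no genome sequence was used. Tags of 19 to 24 nt whose first 18 nt equalled those of a listed sequence were added up to their family. The list held 38 plant families in 8 groups (silencing machinery, auxin pathway, development transcription factors, phase change, copper and laccase, nutrient response, secondary siRNA triggers, other poplar miRNAs). It was written from general knowledge of plant miRNAs, not from an annotation of this clone, and members of a family that differ after the prefix are added together. A further, overlapping list held 4 families reported in phloem sap, and 11 control families (6 of animals and 5 of other plants) measured background. Every other tag was a feature of its own. Tags were not matched to genes, and shares of ribosomal, transfer and other RNA classes were not computed, apart from reads that contain the conserved start of 5.8S rRNA or, at a fixed position, the A box motif of tRNA genes.

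Differences were tested with edgeR 4.0.16 (quasi-likelihood F-test) in R 4.3.3. Counts of all 11 libraries entered 1 fit with the 4 tissues as groups, trimmed mean of M values (TMM) factors, the total reads of 18 to 30 nt as library size, and the default filter on low counts (filterByExpr, minimum count 10, minimum total 15). This left 281063 features, among them 35 plant families. The 4 contrasts were leaf against the mean of cambium, phloem and xylem (called wood tissues here), cambium against phloem, cambium against xylem, and phloem against xylem. A test of any difference among tissues was added. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, over all features and, for families, also adjusted over the list alone. Log2 fold changes are given with a standard error obtained from the fitted change and its F statistic. CPM values are counts per library scaled to a common total after TMM scaling, given as mean ± SD over libraries.

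The families named were those past the threshold over all features, in order of their change and at most 20 per contrast. Outside the families, up to 2 tags in each direction were named per contrast, taken by the size of the change among tags past the threshold with a mean of at least 50 CPM and no overlap between both sides. Families that missed the threshold are named where their group is described.

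Shares of reads by length, by first base, in the 10 most abundant tags and in the listed families, and the number of distinct tags at a common depth of 19159662 reads, were compared on the log2 scale with two-sided exact permutation tests over all assignments of the libraries. These are 18 tests, of 9 measures by 2 comparisons, and their p-values were adjusted together. The smallest p that leaf against wood can give is 0.00606, and the smallest for a pair of tissues is 0.1.

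The groups, lists, tests, contrasts, the naming rule and all alternatives but 1 were set before the data were examined. The alternatives were DESeq2 1.42.0, library totals without TMM, TMM factors computed on the miRNA families only, no filter on low counts, replicate number as a block, families by identity over the whole length or with up to 1 mismatch, and each library left out in turn. For the shares they were distinct tags in place of reads, leaving out the 100 most abundant tags, leaving out tags with 1 read, a lower common depth and another denominator. The alternative without cambium 2 and phloem 1 was added after the data were seen. These libraries stood apart from their tissues over the same features, so leaving them out narrows the spread within tissues by construction. Higher counts in that fit are therefore no independent support. Where 1 xylem library is left out, the remaining one is assumed to vary like the libraries of the other tissues.

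The fit was tested on simulated data drawn from the means and library sizes of these libraries over 281063 features. For leaf against wood tissues, 6% of features raised by 4 times in leaf were found, 48% of those raised by 16 times and 94% of those raised by 64 times. Of features lowered in leaf, 0% were found at 4 and 16 times and 2% at 64 times. For cambium against phloem, 20% of features raised by 64 times were found, 0% of those lowered by 64 times, and 0% at 4 and 16 times in either direction. For cambium against xylem, 0% were found at any of these sizes in either direction. No unchanged feature was called. At each size and direction 50 features were changed, and all unchanged features had the same mean in every tissue. The adjustment is stricter in such data than in the real fit, which called 47384 features between leaf and wood tissues. These rates therefore do not give the power of the reported tests. Shares and permutation tests were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.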

Results

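The series addresses how the small non-coding RNAs of poplar differ among the tissues that take part in wood formation and the leaf. Small RNA libraries were made from leaf (n = 3), from cambium, the dividing cell layer of the stem (n = 3), from phloem, the sugar-conducting tissue outside it (n = 3), and from xylem, the wood side inside it (n = 2). Each library held 19159662 to 25717283 reads of 18 to 30 nt.

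Leaf libraries had the highest mean shares of 21-nt reads and of listed miRNAs. Reads of 21 nt, the usual product of DCL1, made up 51.1% ± 13.9 (SD, n = 3) of leaf reads, 22.6% ± 11.5 (n = 3) of cambium reads, 23.8% ± 11.9 (n = 3) of phloem reads and 17.3% ± 2.10 (n = 2) of xylem reads. The listed miRNA families took 43.2% ± 11.5 of the reads in leaf, 11.97% ± 7.33 in cambium, 16.4% ± 10.3 in phloem and 4.94% ± 0.00108 in xylem. Reads of 24 nt, the length of the siRNAs that guide DNA methylation, reached 39.1% ± 8.72 in cambium, against 16.05% ± 8.09 in leaf, 22.3% ± 9.75 in phloem and 21.04% ± 6.96 in xylem. The ratio of 24-nt to 21-nt reads was 0.367 ± 0.294 in leaf and 1.80 ± 1.62 over the 8 wood libraries.

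In two-sided exact permutation tests of leaf against wood tissues, the unadjusted p was 0.0182 for the 21-nt share, 0.0303 for the ratio of 24-nt to 21-nt reads and 0.0242 for the miRNA share, and each adjusted p was 0.0779, which misses the threshold. The 24-nt share of cambium lay above every phloem library and every xylem library, with the smallest p that these sizes allow (exact p = 0.1 for both). The share of 22-nt reads was 7.94% ± 0.452 in leaf, 9.07% ± 3.71 in cambium, 15.6% ± 15.0 in phloem and 10.3% ± 1.36 in xylem, with no detectable difference among tissues (exact p = 0.892). The phloem mean rests on phloem 3 with 32.8%, while phloem 1 and 2 had 5.28% and 8.77%. The 21-nt difference between leaf and wood rested on abundant tags: without the 100 most abundant tags its exact p was 0.345, and over distinct tags 0.497. Within the wood tissues, cambium 2 and phloem 1 stood apart with 9.35% and 10.2% of 21-nt reads and 3.51% and 4.67% of miRNA reads, below the other libraries of their tissues.

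**Figure D1:**
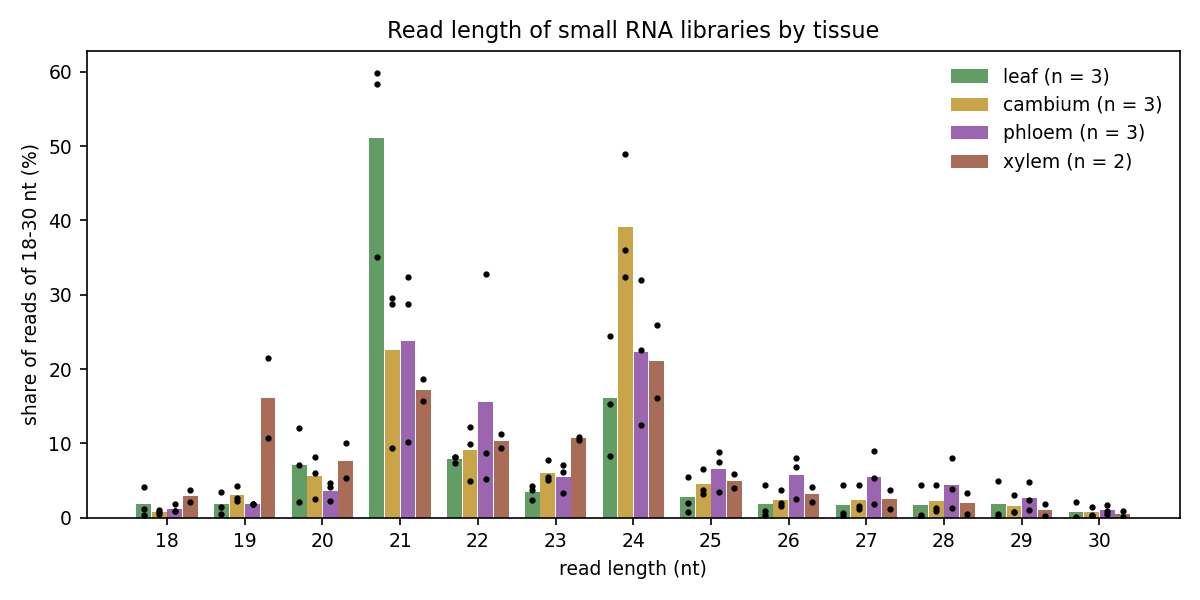
Read length distribution of the 4 tissues: the x axis is read length in nt and the y axis the percent of reads of 18 to 30 nt, with bars for the tissue mean and points for single libraries. Leaf peaks at 21 nt with a mean of 51.1%, cambium at 24 nt with 39.1%, and xylem has 16.1% of its reads at 19 nt.

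The first base of the reads, which goes with the Argonaute protein that binds them, differed among tissues. A first U, the base preferred by AGO1, was found in 83.8% ± 3.35 (SD, n = 3) of the 21-nt reads of leaf, 52.7% ± 8.09 (n = 3) of cambium, 69.2% ± 11.4 (n = 3) of phloem and 37.3% ± 5.29 (n = 2) of xylem. This difference among tissues passed the threshold (exact permutation p = 0.00201, adjusted p = 0.0362) and was the only one of the 18 tests to do so. A first A, the base preferred by AGO4, was found in 57.2% ± 0.401 of the 24-nt reads of leaf, 58.1% ± 1.43 of cambium and 57.3% ± 1.72 of phloem, but in 38.7% ± 0.338 of those of xylem (exact permutation p = 0.0121 for any difference, adjusted p = 0.0779). Without xylem 1, and likewise without xylem 2, the exact p was 0.0668.

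**Figure D2:**
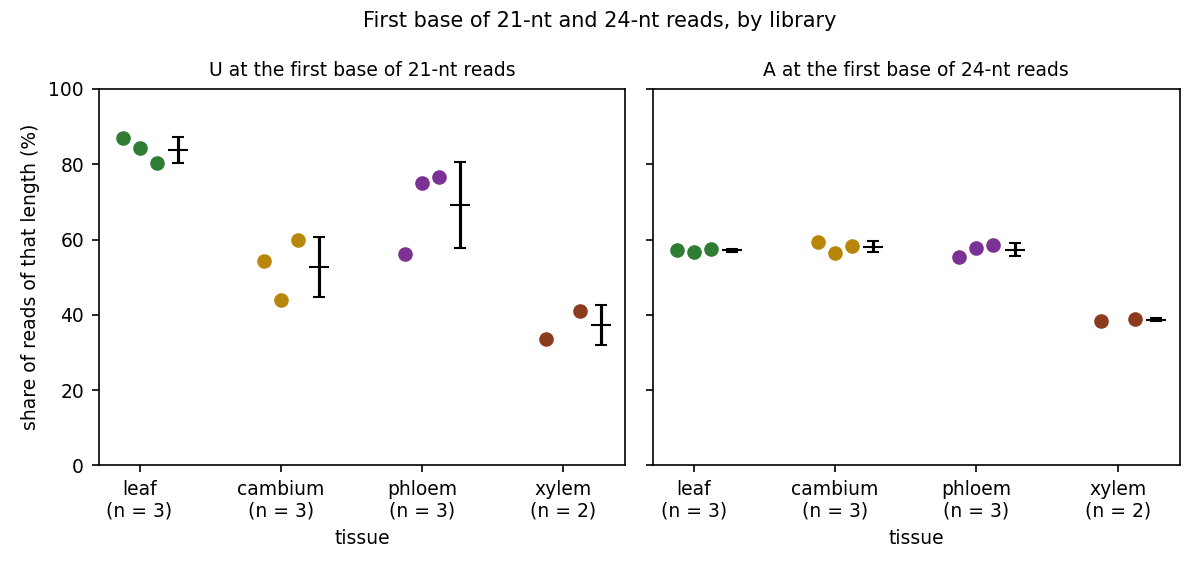
Percent of 21-nt reads that start with U and percent of 24-nt reads that start with A, in each tissue: points are libraries, and the mean with its SD stands beside them. The xylem libraries lie at 38.5% and 38.9% for A at 24 nt, below all other libraries, of which the lowest is at 55.3%.

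Leaf reads were also spread over fewer sequences on average, a difference that misses the adjusted threshold. At a common depth of 19159662 reads, leaf held 2.25e+06 ± 440965 distinct tags, cambium 5.64e+06 ± 1.16e+06, phloem 3.55e+06 ± 1.79e+06 and xylem 4.83e+06 ± 876035. The 10 most abundant tags of a library took 45.7% ± 10.2 of the reads in leaf, 15.9% ± 8.75 in cambium, 26.8% ± 21.8 in phloem and 16.4% ± 5.57 in xylem. For leaf against wood tissues the exact permutation p was 0.0182 for distinct tags (adjusted p = 0.0779) and 0.0424 for the 10 most abundant tags (adjusted p = 0.0955). Phloem 3, with 1.92e+06 distinct tags and 50.3% of its reads in 10 tags, lay within the range of leaf for both. Without cambium 2 and phloem 1 these p-values were 0.0714 and 0.0595.

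With all 11 libraries, edgeR called more features between leaf and the wood tissues than between any 2 wood tissues. With cambium 2 and phloem 1 left out, the 68448 between leaf and wood were fewer than the 69232 between cambium and xylem and the 83231 between phloem and xylem. Of 35 plant families tested, 15 were higher and 4 lower in leaf over all features, and 17 were higher and 5 lower when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted). Increases with the main definition of families were led by miR827 (log2 fold change 7.82 ± 0.97, adjusted p = 0.000818), which targets phosphate transport genes, and miR398 (5.46 ± 0.87, adjusted p = 0.00127), which targets copper/zinc superoxide dismutase. With up to 1 mismatch to the listed sequences miR827 was at 4.68, still past the threshold but below miR398 and miR390. Decreases were found in miR473 (-6.53 ± 0.97, adjusted p = 0.00103), miR530 (-6.02 ± 1.21, adjusted p = 0.00406), miR1446 and miR477. For miR477 the fitted change of -10.25 ± 1.57 (adjusted p = 0.00145) stands against 0 reads in leaf. Its rank among the decreases stays open. The scaling changed this balance: with library totals 8 families were higher and 5 lower, with TMM factors from the families alone 5 were higher and 6 lower, and with DESeq2 17 were higher and 6 lower.

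In the development transcription factor group, 4 of 8 families rose in leaf. miR166, which targets class III HD-ZIP genes of vascular and leaf polarity, was the most abundant family, with 403096 ± 113171 CPM in leaf (SD, n = 3) and 61117 ± 98118 CPM in wood (n = 8), a log2 fold change of 4.83 ± 0.73 (edgeR adjusted p = 0.00108). This change weighs the log levels of the 3 wood tissues equally and so exceeds the ratio of these means, and phloem 3, with 277714 CPM, lay above leaf 1, with 272998 CPM. miR396, which targets growth-regulating factors, had 133772 ± 46753 CPM in leaf and 24891 ± 16636 CPM in wood (2.52 ± 0.73, adjusted p = 0.0294), but its change was -1.33 when only tags identical to a listed sequence over the whole length were counted. miR159, which targets GAMYB genes, rose by 2.48 ± 0.72 (adjusted p = 0.0295), and miR394, which targets an F-box gene, by 2.76 ± 0.68 (adjusted p = 0.0125). The other families of the group did not pass: miR319 (-0.21 ± 0.95), which targets TCP genes, miR164 (-0.16 ± 0.74), which targets NAC genes, miR169 (1.22 ± 0.77), which targets NF-YA genes and was at -1.08 with family TMM factors, and miR171 (-2.16 ± 0.92), which targets GRAS genes. miR171 did pass with family TMM factors (-3.91, adjusted p = 0.0252), with DESeq2 (0.0194) and without cambium 2 and phloem 1 (0.0384). The call of miR166 was lost without xylem 1 (adjusted p = 0.0571), that of miR394 without leaf 3, xylem 1 or xylem 2 (0.0728 to 0.114), that of miR396 without leaf 2, leaf 3, phloem 2, xylem 1 or xylem 2 (0.0561 to 0.205), and that of miR159 without those libraries, cambium 2 or cambium 3 (0.0516 to 0.187).

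In the auxin group, 3 of 5 families rose in leaf. miR390 rose by 5.25 ± 0.80 (edgeR adjusted p = 0.00112), from 18.0 ± 10.0 CPM in wood to 691 ± 594 CPM in leaf, and the tasiARF siRNAs whose production it triggers, and which target auxin response factors, rose by 4.83 ± 0.75 (adjusted p = 0.00119), from 122 ± 102 CPM to 3050 ± 1819 CPM. miR167, which targets other auxin response factors, rose by 3.17 ± 0.59 (adjusted p = 0.00255, and 0.0557 without xylem 1). miR160 (0.44 ± 0.70) and miR393 (-0.35 ± 0.77), which target auxin response factors and auxin receptors, did not pass, and miR160 was negative with library totals (-0.38) and with family TMM factors (-1.57).

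In the copper and laccase group, 3 of 4 families rose in leaf over all features and 4 of 4 when adjusted over the list alone. Beside miR398, with 352 ± 196 CPM in leaf and 10.2 ± 9.22 CPM in wood, these were miR408 (4.18 ± 1.00, edgeR adjusted p = 0.0106, and 0.0585 without xylem 2), which targets plantacyanin and laccases, and miR397 (3.69 ± 0.80, adjusted p = 0.00618), which targets laccases of lignin formation. With family TMM factors miR398 alone of the group passed (adjusted p = 0.0504 for miR408 and 0.0811 for miR397). With library totals miR397 was at 0.0544. miR397 was scarce, with 35 reads in leaf and 11 in wood. miR1444, which targets polyphenol oxidases, passed over the list alone (1.34 ± 0.55, adjusted p = 0.0443), was at -0.36 with family TMM factors, and lost the call without any library except leaf 3 (adjusted p = 0.0588 to 0.184).

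In the nutrient group, 1 of 4 families passed over all features. miR827 had 147 reads in leaf and 3 in wood, a ratio of 218 (95% counting interval 73.0 to 1068). This holds for the main definition alone: with up to 1 mismatch, up to 19 reads were found in a wood library against 34 to 65 in each leaf library, and by whole-length identity 0 reads were found in any library. Animal miRNA families, counted as background, had 180 to 13644 reads each over the 11 libraries, so that miR827 and miR397 lie below that level over all libraries together. Within leaf, miR827 lay above the scarcest of them, miR-1, in each library (34 to 58 against 7 to 50 reads). Adjusted over the list alone, miR395 of sulfate assimilation was higher (1.77 ± 0.65, edgeR adjusted p = 0.0285), but it was at -0.37 with family TMM factors, and miR2111, found in phloem sap under phosphate starvation, was lower (-2.29 ± 0.89, adjusted p = 0.0374, and past the threshold over all features with library totals, family TMM factors and DESeq2). miR399, which targets the phosphate regulator PHO2, did not pass (-0.42 ± 0.58). The call of miR395 was lost without leaf 2, leaf 3, phloem 2 or any cambium or xylem library (adjusted p = 0.0533 to 0.208), and that of miR2111 without leaf 1, leaf 2, cambium 1, cambium 3, phloem 2, phloem 3 or xylem 1 (0.0594 to 0.132). Of the 4 families reported in phloem sap (miR395, miR398, miR399, miR2111), 1 was higher over all features, and 2 were higher and 1 lower in leaf when adjusted over the list alone.

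Among silencing machinery miRNAs, miR162, which targets DCL1, rose in leaf by 2.53 ± 0.56 (edgeR adjusted p = 0.00661), with 6943 ± 1376 CPM against 1187 ± 416 CPM in wood, a call lost without xylem 1 or xylem 2 (adjusted p = 0.104 and 0.0789). miR168, which targets AGO1 (1.32 ± 0.62, at -0.74 with family TMM factors), and miR403, which targets AGO2 (0.29 ± 0.79, at -0.48 with library totals and -1.85 with family TMM factors), did not pass. In the phase change group 1 of 3 families passed: miR172, which targets AP2-like genes, was at 1.89 ± 0.58 (adjusted p = 0.0375), but at -0.15 with family TMM factors, and lost the call by whole-length identity (0.140) and without leaf 2, leaf 3, phloem 2 or any cambium or xylem library (0.0720 to 0.145). miR156 (-0.03 ± 0.60), which targets SPL genes, and miR535 (-0.28 ± 1.77) did not pass. Of the secondary siRNA triggers, 2 of 3 tested families rose: miR482 (2.74 ± 0.70, adjusted p = 0.0156, and 0.0649 to 0.0918 without leaf 2, leaf 3, xylem 1 or xylem 2), which targets disease resistance genes, and miR475 (2.81 ± 0.51, adjusted p = 0.00235), which targets pentatricopeptide repeat genes. With family TMM factors miR482 (1.02, adjusted p = 0.197) and miR475 (1.10, adjusted p = 0.148) missed the threshold, and with library totals miR482 did (0.0681). miR476 did not pass (0.46 ± 0.72) and was at -0.35 with library totals and -1.74 with family TMM factors.

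Among the other poplar miRNAs, 4 of 5 tested families were lower in leaf by edgeR over all features. miR473 had 2.89 ± 1.17 CPM in leaf and 333 ± 280 CPM in wood. miR1446 had 24.8 ± 1.42 CPM in leaf and 194 ± 171 CPM in wood (-2.75 ± 0.73, edgeR adjusted p = 0.0190), and its call was lost without any leaf or xylem library (adjusted p = 0.0502 to 0.123). miR477 had 0 reads in leaf and 2259 in wood. Against a floor of 3 counts per leaf library (mean 0.180 CPM), leaf was at least 59.0-fold below the mean of the wood libraries. That bound rests on xylem (28.2 ± 2.30 CPM) and cambium (8.66 ± 2.34 CPM) and does not hold for phloem (0.905 ± 0.938 CPM). Under the main definition phloem 3, with 2 reads (0.118 CPM), lay below the leaf floor. With up to 1 mismatch it had 731 reads, and the leaf libraries had 0 to 3. miR530 had 2 reads in leaf and 768 in wood, a ratio of 86.4 (95% counting interval 23.8 to 715) under the main definition. With up to 1 mismatch, where leaf 1 had 25 reads, its change was -2.69 and the call was lost (adjusted p = 0.132). By whole-length identity the call was also lost (0.0706), though the change of -7.48 was larger than with the main definition. miR1450 did not pass (0.78 ± 0.54) and was at -0.96 with family TMM factors.

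These directions held unevenly over the scalings. miR827, miR398, miR390, miR166 and tasiARF stayed higher, and miR477, miR473, miR530 and miR1446 lower, past the threshold with TMM, with library totals and with family TMM factors. Every other family called between leaf and wood missed the threshold with family TMM factors. Without xylem 1 the count of families was 10, and without xylem 2 it was 11, in place of 19. In these fits the filter also let in more features (451619 and 451111, in place of 281063), and over the list alone 17 families passed in each, in place of 22, so that calls lost without a xylem library cannot be put down to that library alone. Without cambium 2 and phloem 1 it was again 19, of which 17 were shared.

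**Figure D3:**
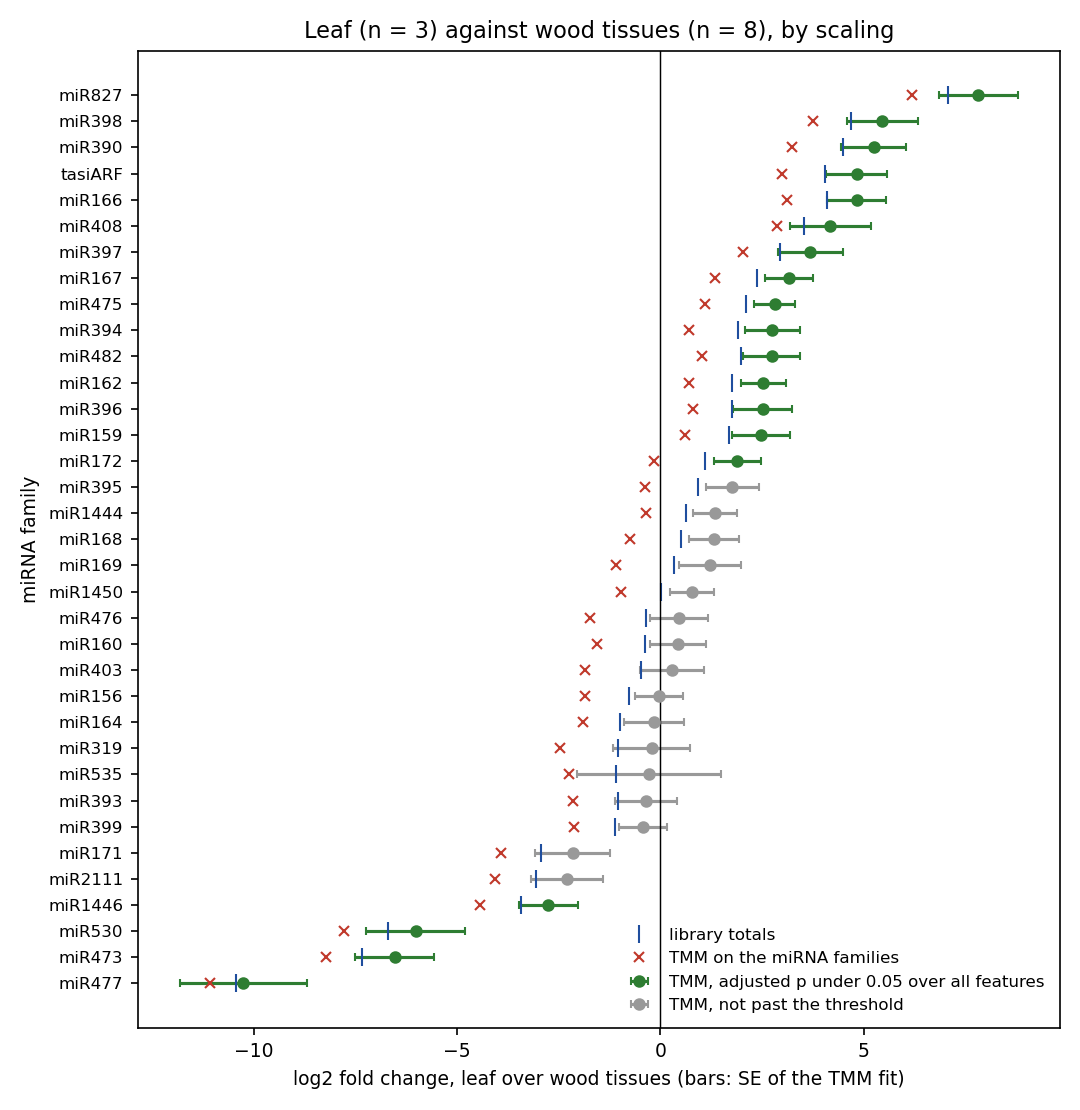
Log2 fold change of 35 miRNA families in leaf against the mean of the wood tissues: points with bars are the change with TMM factors ± SE, green where the edgeR adjusted p over all features is under 0.05 and grey otherwise, with ticks for library totals and crosses for family TMM factors. miR827 is highest at 7.82, miR477, with 0 reads in leaf, is drawn at its fitted -10.25, and miR172, among the families in green, crosses to -0.15 with family TMM factors.

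Over all 281063 features, 47384 differed between leaf and wood tissues by edgeR, 34885 higher and 12499 lower in leaf. The share of tested features that were higher in leaf peaked at 21 nt (29.3%) and 22 nt (23.4%), against 11.2% to 16.1% at 18 to 20 nt and 8.98% at 24 nt. The 22-nt tag TCTCACTACCTTGTCTTTGACG had 770 ± 734 CPM in leaf and 0.569 ± 1.04 CPM in wood (log2 fold change 11.44 ± 1.60, adjusted p = 0.000877), and the 21-nt tag TATTACTAGGAATTAACCTCT had 377 ± 162 and 0.322 ± 0.746 CPM (11.24 ± 1.36, adjusted p = 0.000788). In the other direction, the 22-nt tag TGAACTCTCTCCCTCAACCGCC had 0.701 ± 0.60 CPM in leaf and 193 ± 93.5 CPM in wood (-8.04 ± 1.13, adjusted p = 0.000883), and the 21-nt tag CCTCCAAGGCCTGTTAGAGCT had 1.41 ± 0.746 and 238 ± 75.5 CPM (-7.40 ± 0.93, adjusted p = 0.000788). They were taken from 88 eligible tags higher in leaf and 49 lower, and all 4 kept their call under every alternative. The share of calls that were higher in leaf was 73.6%, but 50.2% with library totals, 28.7% with family TMM factors and 54.8% with DESeq2. The median log2 change of all features was -0.55, -1.26, -2.31 and -0.76 in these fits. Without leaf 2 the count was 19767, without leaf 3 it was 27057, and without leaf 1 it was 30393.

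Within the stem, the libraries did not all sort by tissue. Over the tested features, cambium 1 and 3 correlated with r = 0.904, phloem 2 and 3 with 0.874 and the xylem libraries with 0.839 (Pearson's r of log2 CPM, across features, which are not independent replicates). Cambium 2 was closest to phloem 1 (0.743) and had a mean r of 0.360 with the other cambium libraries, and phloem 1 had a mean r of 0.470 with the other phloem libraries. Both were close to xylem 2, with r of 0.689 and 0.696.

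**Figure D4:**
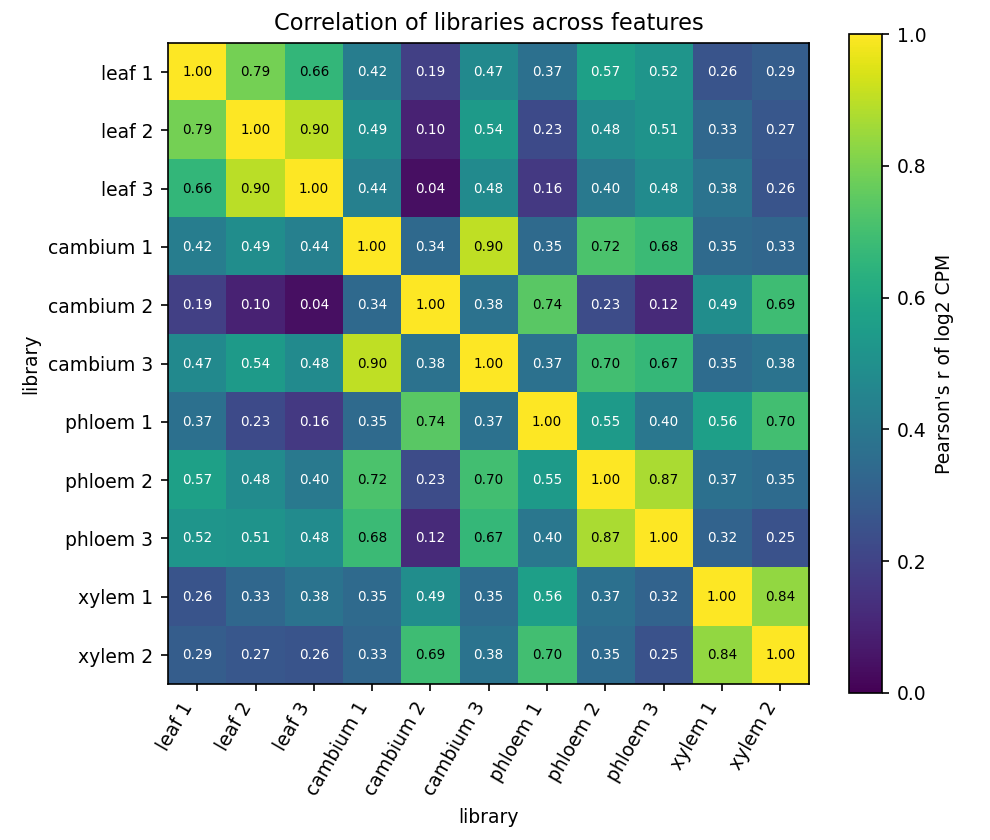
Pearson's r between the 11 libraries over log2 CPM of the tested features, as a heat map with libraries on both axes in order of tissue. Cambium 2 and phloem 1 correlate with each other at 0.743 and with the rest of their own tissues at 0.360 and 0.470 on average.

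Phloem and xylem differed in 10 of 35 families when adjusted over the list alone, 1 higher and 9 lower in phloem. miR166 was higher in phloem, with 147294 ± 125349 CPM (SD, n = 3) against 1312 ± 119 CPM in xylem (n = 2), a log2 fold change of 6.81 ± 1.38 (edgeR, adjusted p over the list = 0.00473). The lower families were led by miR394 (-5.22 ± 1.07), with 19.3 ± 7.75 CPM in phloem and 720 ± 227 CPM in xylem, miR477 (-4.94 ± 1.10), miR171 (-4.67 ± 1.16), with 122 ± 84.0 against 3099 ± 734 CPM, and miR393 of the auxin receptors (-4.15 ± 1.07), with 177 ± 189 against 3146 ± 255.8 CPM. Their adjusted p over the list ranged from 0.00473 for miR394 to 0.0100 for miR393. With up to 1 mismatch miR477 had 257 to 731 reads in a phloem library and 737 and 814 in xylem. With the main definition these were 2 to 48 and 575 and 621, so the size of its change depends on the definition.

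The remaining lower families were miR172 (-3.79 ± 0.86), miR476 (-3.73 ± 1.02), miR169 (-3.24 ± 1.11), miR530 (-3.15 ± 1.06) and miR473 (-3.05 ± 0.89). Sizes depended on phloem 1, without which miR172 was at -4.77, miR476 at -5.32, miR169 at -4.19, miR530 at -4.77, miR393 at -5.63 and miR477 at -6.14. By group, these were 1 of 5 auxin families, 4 of 8 of the development group (miR166 higher, miR169, miR171 and miR394 lower), 1 of 3 phase change families, 1 of 3 secondary siRNA triggers and 3 of 5 other poplar miRNAs. The silencing machinery, copper, nutrient and phloem sap lists had 0 members past the threshold by edgeR over the list alone. Xylem was also the tissue where the 19-nt tag GCGCCTGTAGCTCAGTGGA took 11.4% ± 5.09 of the reads and where the share of 24-nt reads that began with A was lowest.

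Over all features, edgeR called 0 features and 0 families between phloem and xylem, with 57765 features and 12 families at an unadjusted p under 0.05, while DESeq2 called 27387 features and 11 families. Adjusted over the list alone, 1 family was higher and 2 lower with family TMM factors (miR166, miR171 and miR394), 1 higher and 7 lower with library totals, and 2 higher and 13 lower with DESeq2. With up to 1 mismatch 1 was higher and 6 lower, and 3 of the 10 families lost the threshold over the list. There miR169 had 58 to 132 reads in a phloem library and 152 and 113 in xylem. With the main definition these were 2 to 21 and 99 and 78. With the replicate block 1 was higher and 7 lower, and miR169 and miR530 missed the threshold (edgeR adjusted p over the list = 0.0527 for both). Without xylem 1, miR394 and miR477 kept the threshold over the list and the other 8 families were at 0.0526 to 0.146. The call of miR166 was also lost without xylem 2 (0.0996), and those of miR169, miR473, miR476 and miR530 without phloem 2 or phloem 3 (0.0555 to 0.140), of miR169, miR473 and miR530 without xylem 2 (0.0657 to 0.0832), and of miR169 and miR530 without leaf 2 (0.0582). With phloem 1 left out, edgeR called 31137 features and 10 families over all features. Without cambium 2 and phloem 1, 83231 features and 12 families passed over all features, including all 10, and miR403 (-3.75 ± 1.07) and miR408 (3.84 ± 1.04). Leaving out libraries that stand apart from their tissue narrows the spread by itself, so this gain is no further support for the 10.

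**Figure D5:**
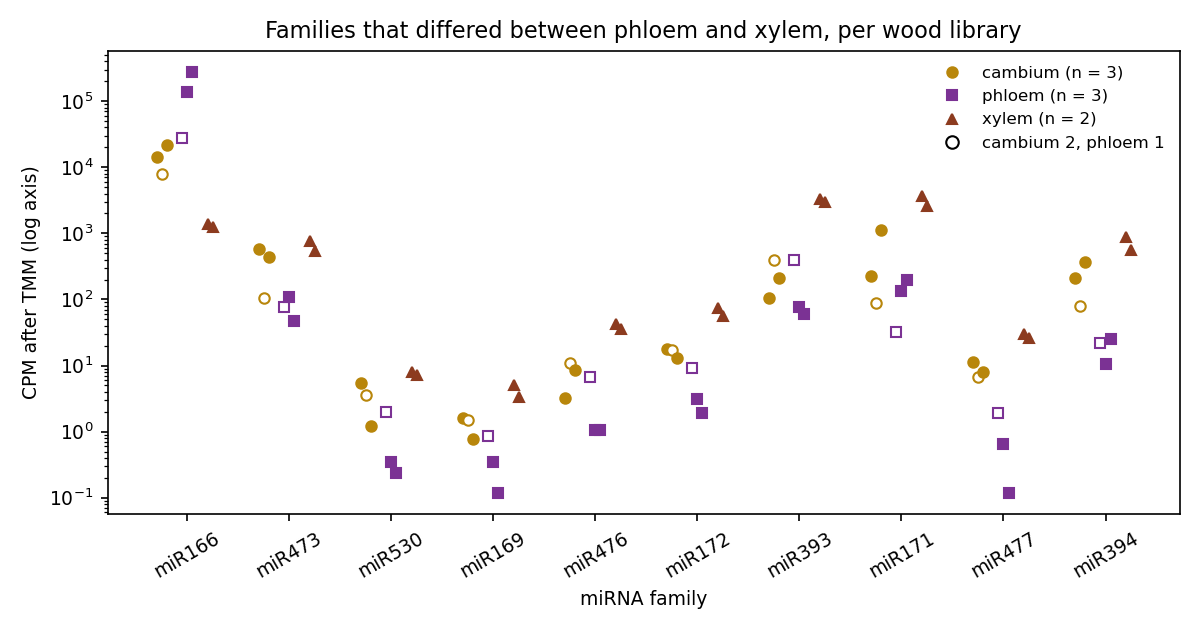
CPM (TMM-scaled, log axis) of the 10 families that passed between phloem and xylem over the list alone, along the x axis, in the 8 wood libraries: symbols are libraries, open for cambium 2 and phloem 1. miR166 has a mean of 147294 CPM in phloem and 1312 CPM in xylem, and miR394 a mean of 19.3 and 720 CPM.

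Between cambium and phloem, no family passed by edgeR over all features or over the list alone. The nearest were miR394 (3.51 ± 0.96), with 219 ± 144 CPM in cambium (SD, n = 3) and 19.3 ± 7.75 CPM in phloem (n = 3), miR166 (-3.31 ± 0.97), with 14810 ± 7039 and 147294 ± 125349 CPM, and miR477 (3.24 ± 0.99). Their adjusted p over the list was 0.0769 for miR394 and miR166 and 0.0818 for miR477. With up to 1 mismatch miR477 had 262 to 2144 reads in a cambium library and 257 to 731 in a phloem library, which overlap. By unadjusted p under 0.05, edgeR had 7 families and 36415 features, and DESeq2 called 6 families and 18554 features. With library totals, 2 families passed over the list alone, while 6 did without phloem 1, 4 without cambium 2 and 4 without leaf 1. Without cambium 2 and phloem 1, 7 families were higher in cambium over the list alone, among them miR477 (4.90 ± 1.09), miR530 (3.91 ± 1.03), miR160 (3.37 ± 1.05) and miR172 (3.01 ± 0.88), while over all features edgeR still called 0 (58642 at an unadjusted p under 0.05).

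Between cambium and xylem, no family passed by edgeR either. The nearest were miR393 (-3.73 ± 1.05), with 237 ± 146 CPM in cambium (SD, n = 3) and 3146 ± 255.8 CPM in xylem (n = 2), miR166 (3.50 ± 1.16), with 14810 ± 7039 and 1312 ± 119 CPM, and miR1444 (-2.32 ± 0.77), each with an adjusted p over the list of 0.113. By unadjusted p under 0.05, edgeR had 7 families and 47186 features, and DESeq2 called 5 families and 21175 features. Without cambium 2 and phloem 1, edgeR called 69232 features, 31414 higher and 37818 lower in cambium, and 3 families over all features, all lower in cambium: miR393 (-4.21 ± 1.179), miR476 (-2.65 ± 0.88) and miR1444 (-2.39 ± 0.86). Over the list alone these missed the threshold in the same fit (adjusted p = 0.0992 for miR393 and 0.159 for both others).

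Across the 4 tissues together, 44261 features and 18 families differed in some way by edgeR, and 23 families when adjusted over the list alone. The count of features was 11087 without leaf 2, 19899 without leaf 3, 21959 without xylem 1, 28651 without xylem 2, 83056 without cambium 2 and 106536 without phloem 1.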

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

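No test in this part was chosen only after the result was seen. The 11 control families, which are not expected in poplar, were counted in the same way as the plant families and compared with a floor of 3 counts per library. Among the 6 animal families, reads above this floor were found for all: miR-143 had 13644 reads over the 11 libraries, miR-21 had 5297, miR-16 had 3913, let-7 had 2856, miR-122 had 302 and miR-1 had 180. Together they made up 9.60 CPM, before TMM scaling, in phloem 1, the lowest library, and 355 CPM in phloem 3, the highest, where let-7 (1121 reads), miR-21 (3270 reads) and miR-16 (2760 reads) each peaked. Of the other-plant families, miR444 had 98 reads, 97 of them in cambium 1 alone, while miR161, miR163, miR158 and miR173 had 0 reads in every library. Over the 11 libraries together, miR827 (147 reads in leaf and 3 in wood) and miR397 (35 and 11), which were called between leaf and wood, lie below the scarcest of these animal families. Within leaf, miR827 lay above miR-1 in each library (34 to 58 against 7 to 50 reads) and above miR-122 in leaf 2 and 3, but not in leaf 1 (55 against 90 reads).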

How the results depend on the processing

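The alternative without cambium 2 and phloem 1 was chosen only after the result was seen; the other alternatives were not. RNA class shares and their matching alternative were not run. Depth limits scarce families (miR397, miR535, miR827, miR530), and the cause of the changes below was not tested except where stated.

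Where an alternative gave a value, the 19 families called between leaf and wood tissues kept their direction with 2 exceptions: miR396 was at -1.33 by identity over the whole length, which leaves out its most abundant tag, absent from the list, and miR172 at -0.15 with family TMM factors. By whole-length identity miR397, miR827 and miR1446 had no value. Of the 19, 12 kept the threshold with library totals, 9 with family TMM factors, 15 without the filter, 18 with up to 1 mismatch (not miR530), 17 with the replicate block and 19 with DESeq2. Leaving out single libraries, 8 of the 19 kept it whichever of the 11 was left out, miR397 kept it in the 9 fits that held it (not without leaf 1 or leaf 2, where it had no value), and of 207 such results 37 lost it and 0 reversed. The 10 families called between phloem and xylem over the list kept their direction in every alternative that gave a value (miR169 had none by whole-length identity), and 2 of them kept the threshold whichever library was left out. Of these 10 families, 7 kept the threshold over the list with up to 1 mismatch and 3 lost it. The 4 named tags kept their call throughout. Among the alternative p-values for shares, lengths and tag numbers, 234 kept direction and side of the unadjusted threshold, 30 lost it, 12 gained it and 2 reversed.

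For features that differ among tissues (44261), family TMM factors gave 27299, the replicate block 20849, DESeq2 114459, the fit without cambium 2 and phloem 1 151289, and single libraries left out 11087 (leaf 2) to 106536 (phloem 1). Leaf against wood tissues (47384) gave 74747 with no filter, where more features are tested, 73344 with DESeq2, and 19767 (without leaf 2) to 53831 (without phloem 1). DESeq2 called 18554, 21175 and 27387 features for cambium against phloem, cambium against xylem and phloem against xylem, where edgeR called 0 of 36415, 47186 and 57765 at an unadjusted p under 0.05. The fit without cambium 2 and phloem 1 called 69232 for cambium against xylem and 83231 for phloem against xylem, the latter at 0 to 31137 (without phloem 1) with single libraries left out.

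Families between leaf and wood (19 over all features, 22 over the list) were 11 and 14 with family TMM factors, and 10 (without xylem 1, where 451619 features were tested) to 20 (without phloem 1) over all features. Cambium against phloem (0) gave 6 with DESeq2 over all features, and over the list 2 with library totals, 4 by whole-length identity, 7 without cambium 2 and phloem 1, 10 with DESeq2 and 0 to 6 (without phloem 1). Cambium against xylem (0) gave 3 without both libraries and 5 with DESeq2 over all features, and over the list 0 without both libraries, 2 by whole-length identity, 6 with DESeq2 and 0 to 1 (without phloem 1). Phloem against xylem gave 12 without both libraries, 11 with DESeq2 and 0 to 10 (without phloem 1) over all features, and over the list (10) 3 with family TMM factors and 2 (without xylem 1) to 12 (without phloem 1).

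Exact permutation p-values between leaf and wood moved as follows. Over distinct tags they were 0.497 for the 21-nt share, 0.679 for the ratio of 24-nt to 21-nt reads and, with the direction reversed, 0.776 for the 24-nt share. Without the 100 most abundant tags they were 0.345 for the 21-nt share, 0.358 for the ratio and, reversed, 0.764 for the 22-nt share. Without cambium 2 and phloem 1 they were 0.0714 for distinct tags and 0.0595 for the 10 most abundant tags. With single libraries left out they were 0.0444 to 0.4 for the 24-nt share, 0.00833 to 0.0889 for the ratio, 0.0167 to 0.0667 for first U, 0.00833 to 0.0667 for distinct tags and 0.0167 to 0.111 for the 10 most abundant tags.

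Exact p-values among tissues without cambium 2 and phloem 1 were 0.0119 for the 21-nt share, 0.0460 for distinct tags and 0.00317 for the miRNA share. The miRNA share had 0.0355 by whole-length identity, 0.0429 over reads of 20 to 24 nt, and 0.0273 to 0.150 with single libraries left out. Distinct tags had 0.0338 at a lower depth and 0.0159 to 0.140 with single libraries left out, and first A at 24 nt had 0.0151 to 0.0668.

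The replicate numbers did not pair the libraries: of 15 same-number pairs 5 deviated together with r above 0.1, the mean r was -0.0618 against 0.0455 for other pairs, and 1 of 11 libraries was closest to one of its own number. With the replicate block, edgeR called 34832 features and 17 families between leaf and wood, exact p was 0.0556 for first A at 24 nt and 0.0486 for distinct tags among tissues, and features among tissues were 20849, as above. Between leaf and wood, miR159 (edgeR adjusted p = 0.0642) and miR172 (0.0662) lost their call with the block. Between phloem and xylem, 8 of the 10 families kept theirs over the list, and miR169 and miR530 did not (0.0527 for both).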

Other observations

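All tests in this part were chosen only after the result was seen, except 2 whose result had not been seen: the correlations over 24-nt tags alone and the first base over shared 24-nt tags.

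Within 11 of 21 families, leaf and wood tissues differed in the tags used. The share of the second most abundant tag among the first and second is a ratio within a library and so does not depend on scaling; of the 21 families, those with at least 1000 reads of the second tag, 11 differed between leaf and wood and 12 among tissues (exact permutation tests, adjusted over 42 tests), and in 10 the leaf and wood libraries did not overlap, which chance gives for 1.21%. In miR396, which targets growth-regulating factors, TTCCACAGCTTTCTTGAACTG made up 2.23% ± 1.45 (SD, n = 3) in leaf and 57.2% ± 23.2 (n = 8) in wood, beside TTCCACAGCTTTCTTGAACTT (adjusted exact p = 0.0159). In miR166, TCTCGGACCAGGCTTCATTCC made up 17.4% ± 1.28 in leaf, 38.1% ± 1.38 in phloem, 78.9% ± 9.87 in cambium and 78.4% ± 11.2 in xylem, beside TCGGACCAGGCTTCATTCCCC (adjusted exact p = 0.0123 among tissues). In the opposite direction, TGACAGAAGAGAGTGAGCAC made up 68.0% ± 23.5 of the miR156 pair in leaf and 9.97% ± 5.57 in wood, and TGCCAAAGGAGAATTGCCCTG 93.4% ± 2.30 of the miR399 pair in leaf and 30.9% ± 19.1 in wood (adjusted exact p = 0.0159 for both). The miR156 and miR399 families as a whole had not differed between leaf and wood.

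A pair of abundant 21-nt tags outside the list, CAGAATTGCAGTGCCTTGATT and TCAGGGCACTGCAATTCTAAA, can pair over 19 positions, with 17 Watson-Crick pairs, 1 G-U pair, 1 unpaired position and 2-nt overhangs, the geometry of a Dicer-like product. The first made up 84.5% ± 11.8 of the pair in leaf (SD, n = 3), 81.7% ± 7.76 in phloem (n = 3), 49.7% ± 37.1 in xylem (n = 2) and 17.7% ± 12.8 in cambium (n = 3), so that the more abundant strand was the other one in cambium (exact permutation p = 0.0198 among tissues). The 22-nt tag GAATTCCACCACGTTCCCGTGG took 26.004% of the reads of phloem 3 and 0.130% to 3.04% elsewhere.

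Cambium 2 and phloem 1 lie closer to each other (r = 0.743) than to their own tissues. An exchange of their labels needs cambium 2 to lie closer to phloem 2 and 3 than to the other cambium libraries, and its mean r was higher with its own tissue by 0.184 (0.360 against 0.176). Fragments of structural RNA would leave the 24-nt tags in order, but over these tags alone the mean r with the own tissue was at most 0.180, below the 0.490 of the lowest other library. This argues against such fragments as the whole cause, but not against a part: reads that contain the conserved start of 5.8S rRNA were most frequent in these 2 libraries (3.46% in phloem 1 and 1.98% in cambium 2, against at most 1.56% elsewhere), and phloem 1 had the highest share of 26-nt to 30-nt reads (31.6%). RNA mostly from xylem would bring the leading 19-nt tag of xylem to at least 3.89% of the reads, while the higher of both libraries had 1.60%. This share alone cannot decide the question, since it also depends on the yield of 19-nt reads. Among 19-nt reads the tag made up 70.6% in cambium 2 and 50.4% in phloem 1, against 69.9% and 72.7% in xylem. Over 26-nt to 30-nt tags both libraries were closest to xylem 2 (r = 0.829 and 0.807). Over 24-nt tags they were closest to each other (0.755). Over 21-nt tags cambium 2 was closest to xylem 2 (0.835) and phloem 1 to cambium 2 (0.825). Of the 24-nt reads, 56.5% began with A in cambium 2 and 55.3% in phloem 1, against 38.5% and 38.9% in xylem. Where low first A is a trait of xylem RNA, these values argue against mostly xylem RNA among the 24-nt reads of both libraries. A smaller part of xylem RNA was not tested. What sets these libraries apart stays open, and no biological explanation was tested.

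In xylem, 24-nt reads began with A in 38.7% of cases, against 55.3% in the lowest other library. Neither a few abundant tags nor fragments from outside the shared siRNA tags account for the whole gap, since the share was 38.6% without the 100 most abundant tags and 41.8% over 768703 tags shared with the other tissues, where the lowest other library had 58.4% (exact permutation p = 0.0182, the smallest of 55 splits). Xylem had already been seen to be lowest over all 24-nt reads, and these tags held 59.3% and 54.5% of them in xylem 1 and 2. This p is therefore no separate support for the difference. Loss of the first base from tags that start with A would need the intact share of such tags to fall to 0.467 of that in the other libraries, and the lower xylem library stood at 0.685. Trimmed forms were still more frequent in xylem, at 0.549 per intact tag against 0.163 elsewhere. For tags with another first base they were at 0.906 in xylem and 0.649 elsewhere on average, with overlapping ranges (0.656 to 1.16 and 0.252 to 0.988). Loss from those tags would raise the share of A and so work against the gap. Whether first-base loss accounts for any part of the gap was therefore not settled. A difference between tissues in the Argonaute proteins that bind 24-nt siRNAs remains open and was not tested.

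The 19-nt tag GCGCCTGTAGCTCAGTGGA took 11.4% ± 5.09 of the reads in xylem (n = 2), 2.02% ± 0.801 in cambium (n = 3), 0.643% ± 0.282 in phloem (n = 3) and 0.0847% ± 0.0724 in leaf (n = 3), with an exact permutation p of 6.49e-05 among tissues. A larger yield of short reads alone is argued against for leaf, where the tag made up 5.58% of the 19-nt reads against 71.3% in xylem. For cambium, with 66.0% ± 6.86, the shares overlap those of xylem. More 19-nt reads in xylem (16.1% against 3.04%) could thus be the whole difference between these tissues, but the tag itself makes up most of these reads. The other 19-nt reads took 4.69% ± 2.51 in xylem and 1.02% ± 0.325 in cambium. The tag holds the A box motif of tRNA genes from position 8. Reads with the motif at that position took 14.5% ± 5.51 in xylem, 2.96% ± 0.894 in cambium, 1.1975% ± 0.856 in phloem and 0.549% ± 0.374 in leaf (exact permutation p = 0.00143 among tissues), but without this tag 3.07% ± 0.421 in xylem, with p = 0.0923. The transcript itself was not identified.

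The libraries were regrouped to see whether other splits give as many differences. For leaf against wood tissues, 1 of 24 splits, the real one, gave as many features, with 47384 against at most 3168 in the others. Likewise 1 of 24 gave as many families over the list, with 22 against at most 6. The real split was thus the highest of those drawn for both. The other splits also mixed the labels of the wood tissues, which can widen the fitted spread and lower their counts. They therefore cannot exclude chance. For cambium against phloem the 10 splits are too few for a share under 0.05. The real split gave 0 features, so that every split had to give as many or more, and the comparison decides nothing. The highest other gave 11298, while families were 0 in the real split and at most 0 in the others. Of the 4 splits that put cambium 2 and phloem 1 on the same side, 2 gave 11298 and 11212 features and 2 gave 0. All remaining splits gave 0 features, like the real one. The 2 splits with far more features may reflect a structure of the samples other than tissue, which was not tested. Placing this pair together was not enough to give such counts.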
